A study of Homo sapiens with 71 samples.

How the data were processed

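Peripheral blood mononuclear cells, the lymphocytes, monocytes and dendritic cells of blood, were taken in the morning and in the evening from healthy persons and from patients with severe obstructive sleep apnoea (OSA), in whom the airway closes repeatedly during sleep. The patients were sampled before treatment and again after short-term and after long-term continuous positive airway pressure (CPAP), which keeps the airway open with a mask. Poly(A) RNA was sequenced as paired-end reads, per the labels' protocols. The 71 libraries came from 10 healthy persons and 9 patients and form 8 groups, named in the labels. Libraries of one person share a number in the labels, and the series' design states that the treated patients are the same as the untreated ones, so the person number pairs libraries within the healthy cohort and within the patient cohort but never across them. Times of day were taken from the titles. A suffix of the library names goes with opposite times in untreated and treated patients, and with either time in healthy persons, and its meaning is not given in the sources used here.

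The authors deposited 1 table of 30200 genes by gene symbol. The submitters' processing notes name kallisto and DESeq2, with no versions, and the GRCh38 build; the annotation is not given in the sources used here. The table is described as normalized counts, but from its values the deposited unit was taken to be TPM, a share of all transcripts after division by transcript length: the columns sum to between 960721 and 979607, and short abundant genes take the largest shares. The tests had been fixed before the data were examined on the assumption of normalized counts, and the same limma test was kept for TPM because it does not need counts. TPM carries no read number, so the depth of each library is unknown and no counting interval or detection floor is given. A fold change is on the log2(TPM + 1) scale, which understates the change of low genes, and a TPM value is a share, so a rise of abundant transcripts lowers the others.

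All Y-linked genes, with XIST and TSIX, were left out before any test, 380 genes in all. Genes with at least 10 TPM in at least 8 libraries were tested, which left 8884. Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend and robust variances), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Patients against healthy persons were compared with the 2 groups alone. Comparisons within persons had the person as a block and used persons with both libraries, 8 or 9 pairs. Whether a time-of-day difference itself differed was tested on evening minus morning differences per person. The pairing was checked on deviations from the group means: the lowest correlation of any 2 libraries of a pair was between 0.15 and 0.46 over the 10 paired comparisons, and the median was between 0.38 and 0.60. In a check for mixed-up samples with 39 genes whose level follows genotype, 0 of the 69 libraries that have a second library of the same person lay closest to another person.

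The genes named were fixed by a rule: among those passing, with a mean of at least 50 TPM in 1 of the 2 groups and the same direction in at least 75% of persons in paired fits, the 10 higher and 10 lower with the smallest p; passing members of the fixed lists, up to 4 per list and direction; where fewer than 5 genes passed, the 3 higher and 3 lower with the smallest unadjusted p; and fixed clock, cortisol-responsive and inflammatory genes in every comparison of their kind. Immunoglobulin and T cell receptor segments, HLA-DR and HLA-DQ genes and a few genes that follow genotype were not named. Of 32 gene lists fixed beforehand, 29 had at least 3 tested members. Those of proliferation, mature neutrophils, and basophils and eosinophils had 2, 1 and 0 and were not tested. Lists were tested with camera in limma at a preset inter-gene correlation of 0.01, and again with an estimated correlation. An exact test of each list's mean log2 value per library, by sign changes within persons or by reassigning persons to groups, was added after the data had been seen, as was the average over a patient's visits. Gene positions are from RefSeq on GRCh38.

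The fit was tested on simulated values drawn from the real means and SDs of the 8884 genes, with known changes added. Each gene was drawn independently, so the false calls given here do not cover genes that vary together, as real genes do. For long-term CPAP against no treatment in the evening it recovered 91.0% of genes changed by 1 log2 unit and 58.0% of those changed by 0.5, with 4 false calls. For OSA against healthy in the evening it recovered 84.0% and 36.0%, with 11 false calls. Alternatives fixed beforehand were another pseudocount, no low-value filter, quantile normalization, no person block, 1 fit of all 8 groups, both times of day together, and covariates for monocytes against T cells and for platelets. Between 2 visits of the same patients, the fit of both times together takes the 2 libraries of a visit as no closer than libraries of different visits. Its counts between visits can therefore be too high. Added afterwards were a filter at 1 TPM, a correction for transcript GC content and length (GENCODE 29 sequences, 97.2% of the tested genes matched) that also makes library means equal, for long-term CPAP against no treatment in the evening the same correction with library means kept and equal means alone, list means without each person in turn and after the GC correction, and leaving out the 2 healthy libraries with the lowest correlation with the others. Figures were drawn with matplotlib 3.10.9. The labels give no age, sex, weight or sequencing batch, so none of these entered a fit, and each treatment stage was a later visit, so treatment and visit cannot be separated. Apart from a visit prefix, library names begin with D in all patients and with AMC, C, CB or F2D in healthy persons. The meaning of these series is not given, and they cannot be separated from the difference between patients and healthy persons.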

Results

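RNA of peripheral blood mononuclear cells was profiled in 71 libraries. Healthy persons gave 9 morning and 9 evening libraries, untreated OSA patients 8 morning and 9 evening libraries, and the same patients 9 libraries at each time after short-term and 9 after long-term CPAP. Each library held between 12613 and 14497 genes at 1 TPM or more. The healthy group was not uniform in this: libraries named CB held between 13602 and 14497, and those named C between 12613 and 13322. Sequencing depth is unknown.

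The first question was whether untreated patients differed from healthy persons. Nonclassical monocyte genes and cytotoxic effector genes, the granzymes and other killing proteins of NK cells and CD8 T cells, lay on the higher side in patients. The 10 nonclassical monocyte genes had a median log2 fold change of 0.55 in the morning and 0.49 in the evening, and the 15 cytotoxic genes 0.36 and 0.42. Camera called both lists higher at both times (adjusted p between 0.00020 and 0.00086), but with an estimated correlation the adjusted p was 0.97 in the morning and 0.88 in the evening, and no list passed the exact test, whose smallest adjusted p was 0.53. Without healthy morning replicate 3 the morning mean of the nonclassical list differed by 0.38, against 0.58 with it. Log2 fold changes increased with transcript GC content (Spearman rho across genes, which are not independent, 0.35 and 0.26), and after the GC and length correction the nonclassical means differed by 0.49 and 0.45, against 0.58 and 0.53 before, and the cytotoxic means by 0.30 and 0.47, against 0.37 and 0.52. No single gene passed in limma, with 0 of 8884 in the morning (830 at an unadjusted p under 0.05, 444 expected) and 0 in the evening (1021). With the person as a correlated block, 60 genes passed with both times in one fit, and 14 and 5 in 1 fit of all 8 groups. Nearest to passing in the morning were TICAM1, FGFRL1 and GIMAP1 on the higher side (log2 fold changes 0.72, 0.71 and 0.53) and ZNF638, ITGB3BP and ZUP1 on the lower (-0.56, -0.68 and -0.54), with adjusted p of 0.18 or more. In the evening they were APOBEC3C, the chemokine receptor gene CXCR3 and SNX20 (0.70, 1.02 and 0.51), and the p53 regulator MDM2 and GLMN (-0.56 and -0.58), with adjusted p of 0.21 or more. HMOX1, which encodes a haem-degrading enzyme, averaged 71.8 TPM in patients and 49.9 in healthy persons in the morning (log2 fold change 0.67 ± 0.32 SE, adjusted p = 0.53) and 72.9 and 54.0 in the evening (0.42 ± 0.19, adjusted p = 0.41). The hypoxia-responsive VEGFA differed by 0.27 and -0.01, and the interferon-induced IFI44L by 0.02 and 0.38. The cytokine genes had wide errors: IL1B differed by 0.30 and -0.63, TNF by 0.03 and -0.54, and CXCL8 by 0.73 and -0.29, with SEs between 0.72 and 1.09. None of these fixed genes passed.

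Treated patients were compared with healthy persons in the same way. Under short-term CPAP the 10 nonclassical monocyte genes had a median log2 fold change of 0.60 in the morning and 0.45 in the evening, and the 15 cytotoxic genes 0.32 and 0.48. Camera called both lists higher at both times, with adjusted p between 7.5e-05 and 0.0020. In the morning each had an adjusted p = 0.93 with an estimated correlation, and in the evening 0.63. The GC rho was 0.29 and 0.26, and after the correction the nonclassical means differed by 0.54 and 0.48, against 0.62 and 0.52, and the cytotoxic means by 0.33 and 0.46, against 0.37 and 0.46. Under short-term CPAP in the evening 26 genes were lower and 0 higher. They included EHMT1, a histone methyltransferase (66.4 against 101 TPM, log2 fold change -0.58 ± 0.11 SE), the Elongator subunit ELP2 (-0.64 ± 0.13), the RNA-binding RBM6 (-0.49 ± 0.10), the mitochondrial protease PITRM1 (-0.43 ± 0.09) and MSL3 (-0.45 ± 0.09), each at an adjusted p of 0.036. Under quantile normalization, and after correction for GC content and length, the count was 0, and without the 2 healthy libraries that correlate least with the rest it was 17. With no low-value filter it was 7, with cell mixture covariates 70 and with both times in one fit 251. In the morning 0 genes passed in limma (1094 unadjusted), but with the person as a correlated block 132 did in 1 fit of all 8 groups and 251 with both times in one fit. The nearest were C16orf54, APH1A and C1orf122 (0.61, 0.55 and 0.47), and ITGB3BP, ZNF141 and WDR19 (-0.56, -0.99 and -0.75). CXCL8 differed by 2.05 ± 0.85 in the morning and 1.96 ± 1.06 in the evening, with adjusted p of 0.36 and 0.41. IL1B differed by 0.99 and 0.95, TNF by -0.71 and -0.68, HMOX1 by 0.76 and 0.45, VEGFA by 0.32 and -0.02 and IFI44L by -0.11 and 0.17, and none passed.

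Under long-term CPAP, B cell and naive T cell genes lay below and nonclassical monocyte and cytotoxic genes above the healthy values. The 13 B cell genes had a median log2 fold change of -0.66 in the morning and -0.71 in the evening. When adjusted over the list alone, 7 of them were lower in the morning and 13 in the evening, but 0 passed over all genes. The mean of the list was 4.62 ± 0.48 (SD, n = 9) against 5.47 ± 0.43 in healthy evenings on the log2 scale, and its exact adjusted p was 0.054. Camera gave adjusted p of 1.2e-10 and 5.6e-09, and 0.27 and 0.44 with an estimated correlation. The medians were -0.62 and -0.41 for the 9 naive T cell genes, 0.74 and 0.50 for the 10 nonclassical monocyte genes and 0.41 and 0.55 for the 15 cytotoxic genes. Camera called these 3 lists at both times, and their adjusted p with an estimated correlation were 0.27 each in the morning and 0.77, 0.44 and 0.44 in the evening. The GC rho was 0.36 and 0.50. After the correction the B cell means differed by -0.73 and -0.81, against -0.69 and -0.84, the naive T cell means by -0.58 and -0.38, against -0.58 and -0.48, the nonclassical means by 0.72 and 0.61, against 0.78 and 0.66, and the cytotoxic means by 0.41 and 0.59, against 0.44 and 0.55. No gene passed in limma at either time, with 634 in the morning and 1640 in the evening at an unadjusted p under 0.05. With the person as a correlated block 3 and 108 did in 1 fit of all 8 groups and 59 with both times in one fit. The nearest in the morning were ASCL2, IFITM3 and the cytotoxic-lineage factor TBX21 (0.92, 1.23 and 0.72) and NUP88, ADPRM and RPL21 (-0.50, -0.65 and -0.52; RPL21 is uncertain because near-identical copies can share its reads), and in the evening SH3BGRL3, PPP1R18 and RTL8C (0.55, 0.51 and 0.46) and RUBCNL, AFF3 and RALGPS2 (-1.01, -1.24 and -1.08). HMOX1 differed by 0.76 and 0.55, VEGFA by 0.42 and -0.35, IL1B by 0.44 and -0.41, TNF by -0.43 and -0.50, CXCL8 by 0.50 and -0.41, and IFI44L by 0.12 and 0.10, none passing.

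To see whether the patient-against-healthy differences stayed after treatment, log2 fold changes were correlated across the 8884 genes, which are not independent. In the evening the correlation between untreated and long-term CPAP patients, each against the same healthy libraries, was 0.59, and between untreated and short-term CPAP patients 0.78. Simulated groups of the same patients with all group means removed, so with no difference from healthy persons at any visit, gave 0.74 and 0.79. Shared persons and shared healthy libraries alone thus give such correlations, which by themselves do not show whether differences stayed. With the healthy libraries split between the comparisons the averages were 0.24 and 0.32. The covariances were 0.045 and 0.055, against 0.026 and 0.030 simulated, of which the upper 95th percentiles were 0.051 and 0.048. In the morning the correlations were 0.65 and 0.80, against 0.71 and 0.77 simulated and 0.21 and 0.36 with split controls. The morning covariances were 0.042 and 0.056, against 0.029 and 0.030 simulated, of which the upper 95th percentiles were 0.054 and 0.053. At both times the short-term covariance lay above its percentile and the long-term one below it. The simulation drew deviations from means of 8 or 9 libraries without correcting for their number, which makes its covariances too small. Each percentile also rests on 100 draws. The short-term values lie too little above their percentiles for this to show whether differences stayed.

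Short-term CPAP was then compared with no treatment in the same patients. In the evening CXCR4, a chemokine receptor gene that holds lymphocytes in tissue, rose in 9 of 9 patients from 105 to 318 TPM (log2 fold change 1.55 ± 0.17 SE, adjusted p = 0.0057). The early activation marker gene CD69 rose in 9 of 9 from 27.1 to 89.7 TPM (1.69 ± 0.21, adjusted p = 0.015), and the kinase gene SGK1 in 9 of 9 from 26.5 to 56.7 TPM (1.09 ± 0.17, adjusted p = 0.035). RGS1 and TIPARP, which fall outside the naming rule and were picked after their values were seen, completed the 5 higher genes (2.31 and 0.68), and 0 genes were lower. CXCR4 lies on chromosome 2 from 136114349 to 136118149, CD69 on chromosome 12 from 9752486 to 9760901 and SGK1 on chromosome 6 from 134169256 to 134318112. Of 15 tested glucocorticoid response genes 2 rose, or 8 when adjusted over the list alone, with a median log2 fold change of 0.67. Among 17 NF-kB inflammatory genes 0 passed over all genes, and 7 were higher and 1 lower when adjusted over the list alone. Camera called both lists higher (adjusted p 5.9e-14 and 5.4e-08), and the adjusted p was 0.26 and 0.27 with an estimated correlation. The exact tests of the list means, higher in 7 and 8 of 9 patients, had an adjusted p of 0.23 each. Of 13 B cell genes 7 were lower over the list alone and 0 over all genes, and camera called the list lower (adjusted p = 1.7e-06, 0.66 with an estimated correlation). IL1B differed by 1.58 ± 0.32 and was higher in 9 of 9 patients, and CXCL8 by 2.25 ± 0.59 in 8 of 9, but their adjusted p were 0.13 and 0.26. VEGFA differed by -0.01, HMOX1 by 0.03, TNF by -0.14 and IFI44L by -0.21, none passing. Without the person block the count was 3, without a low-value filter 0, and with both times in one fit 311.

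In the morning no gene passed between short-term CPAP and no treatment (limma, 761 unadjusted, 8 pairs), but 311 did with both times in one fit and the person as a correlated block. METRNL, the glucose transporter gene SLC2A3 and ANKRD30BL (0.51, 0.50 and 0.53) and CORO1B, ZNF12 and TMOD4 (-0.41, -0.49 and -0.47) were nearest, with adjusted p of 0.30 or more. CXCL8 differed by 1.24, IL1B by 0.69, TNF by -0.77, IFI44L by -0.36, HMOX1 by 0.06 and VEGFA by 0.02. The 16 platelet genes had a median of 0.26 (camera adjusted p 4.1e-08, 0.98 with an estimated correlation), higher in 5 of 8 patients, and the list mean differed by 0.26, or by 0.12 without the patient of untreated morning replicate 8.

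Long-term CPAP against no treatment in the evening gave 402 lower and 41 higher genes. B cell genes fell together: 10 of 13 passed, all lower, and 12 when adjusted over the list alone. CD79A, a subunit of the B cell receptor, fell from 183 to 108 TPM (log2 fold change -0.76 ± 0.14 SE, adjusted p = 0.022, 8 of 9 patients) and CD79B from 109 to 69.4 TPM (-0.61 ± 0.11, adjusted p = 0.019). The transcription factor gene SPIB fell by 0.82, FCRLA by 0.86, BANK1 by 0.90 and TCL1A, a marker of naive B cells, by 1.30, each in 9 of 9 patients. FCMR, the receptor for IgM (221 to 146 TPM), POU2AF1 and ST6GAL1 were also lower. CD79A lies on chromosome 19 from 41877279 to 41881372 and CD79B on chromosome 17 from 63928740 to 63932331. Camera gave the B cell list an adjusted p of 5.7e-09, against 0.86 with an estimated correlation, and the list mean, lower in 8 of 9 patients, differed by -0.83 ± 0.53 (SD, n = 9; exact p = 0.0078, adjusted 0.11).

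Naive T cell genes were on the same side, with 2 of 9 passing, CCR7 (-0.47 ± 0.10, a lymph node homing receptor gene) and NELL2 (-0.43), and 8 lower when adjusted over the list alone. The list mean, lower in 9 of 9 patients, differed by -0.28 (exact p = 0.0039, adjusted 0.11; camera adjusted p = 0.010, 0.86 with an estimated correlation). The 13 mitochondrially encoded genes, which can follow RNA quality, had a median of 0.32 (camera adjusted p = 9.1e-08, 0.86 with an estimated correlation) and a mean higher in 6 of 9 patients. Among 13 T cell genes IL7R and CD3G fell (-0.52 and -0.50), and 3 were lower when adjusted over the list alone. MYC, the growth regulator, fell from 43.9 to 24.4 TPM (-0.83 ± 0.10, adjusted p = 0.0032), HSPA8 and HSP90AB1 by 0.85 and 0.46, and the glycolytic genes PGK1 and ALDOC by 0.51 and 0.34. BIRC3, NFKB1, IFIT5, TXNRD1, CRY2 and the cortisol-responsive FKBP5 (28.0 to 18.6 TPM) were lower as well. Of 52 ribosomal protein genes 4 fell, also 4 when adjusted over the list alone, with RPS27, RPL10A and RPLP0 among them. RPL21 (3328 to 2216 TPM) and EEF1G also fell, but both have near-identical processed copies in the genome, so their values are uncertain. The genes CYB561A3 and CD82 completed the lower genes named. The higher genes were SCO2, an assembly factor of cytochrome oxidase (86.3 to 131 TPM), GBP2, ABCA2, SLC27A3, the myeloid transcription factor gene SPI1 (456 to 612 TPM), ZSWIM8, GPR108, TSPOAP1, CXorf65, RNF31 and TNFAIP2, with log2 fold changes between 0.34 and 0.81. VEGFA differed by -0.34, HMOX1 by 0.13, IL1B by 0.21, TNF by 0.04, CXCL8 by -0.12 and IFI44L by -0.28, none passing. Log2 fold changes increased with transcript GC content (Spearman rho 0.29 across genes, which are not independent), and after correction for GC content and length, which also makes library means equal, 194 genes were lower and 187 higher, of which 218 were among the 443. With the library means kept, that correction gave 499 lower and 70 higher, and equal means alone gave 160 and 144. Quantile normalization, which moved the median log2 fold change of all genes from -0.11 to 0.003, gave 146 lower and 105 higher, and without the person block 0 genes passed. The count was 8 with no low-value filter, 199 with cell mixture covariates, and with the person as a correlated block 1301 in 1 fit of all 8 groups and 2418 with both times in one fit.

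In the morning the same comparison gave 4 lower and 3 higher genes in 8 pairs. RCN3, encoding a calcium-binding protein of the endoplasmic reticulum, rose from 39.1 to 64.5 TPM (0.68 ± 0.11, adjusted p = 0.036) and ABCA2 from 89.3 to 127 (0.52 ± 0.09), while the chromatin remodelling gene SMARCD2 fell from 85.4 to 46.9 (-0.86 ± 0.12, adjusted p = 0.019), each in 8 of 8 patients. Of 13 B cell genes 0 passed over all genes and 7 were lower when adjusted over the list alone, with a median of -0.62 (camera adjusted p 8.8e-08, 0.89 with an estimated correlation). VEGFA, HMOX1, IL1B, TNF, CXCL8 and IFI44L differed by 0.05, 0.05, -0.02, -0.56, -0.46 and -0.22, none passing. The GC and length correction gave 119 higher and 82 lower genes and quantile normalization 98 and 75. The count was 0 with no low-value filter or with cell mixture covariates, 1 without the person block, and with the person as a correlated block 88 in 1 fit of all 8 groups and 2418 with both times in one fit.

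**Figure D1:**
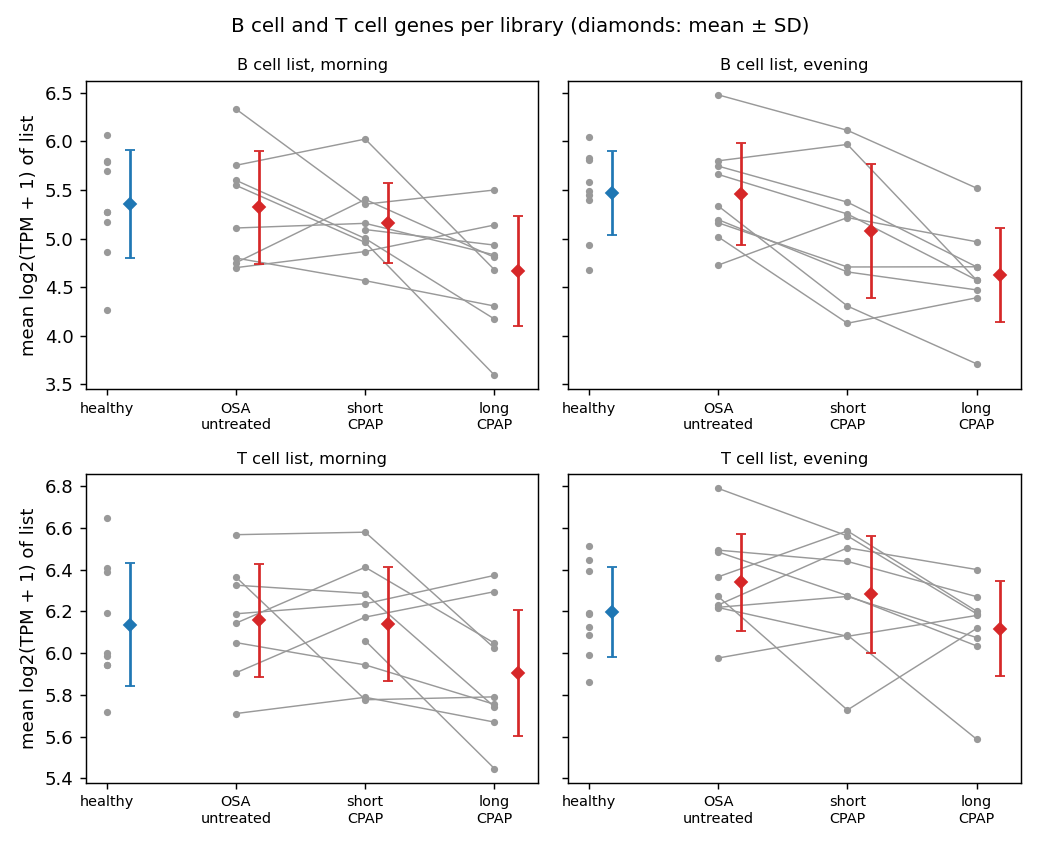
Mean log2(TPM + 1) of the 13 B cell and 13 T cell genes in each library, by time of day and condition; grey points are libraries, lines join one patient's visits, and diamonds with bars are means ± SD. In the evening the B cell mean is 5.46 before treatment, 5.08 after short-term and 4.62 after long-term CPAP, and the T cell mean 6.34, 6.28 and 6.12.

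Between short-term and long-term CPAP the evening count was 425 lower and 303 higher genes. CXCR4 fell from 318 to 109 TPM (-1.52 ± 0.22 SE, adjusted p = 0.010) and CD69 from 89.7 to 33.5 (-1.39 ± 0.22, adjusted p = 0.012), each in 9 of 9 patients. Of 15 glucocorticoid response genes 6 fell, or 9 when adjusted over the list alone, among them TSC22D3 (-0.76), KLF9 (-0.74) and SOCS1 (-0.80), and the clock gene PER1, a member of both lists, fell by 1.14. Of 20 hypoxia response genes 5 fell, or 9 over the list alone, with PGK1 (-0.67 ± 0.09), MXI1, the glucose transporter gene SLC2A1 and ENO1 among them. Of 20 heat shock and unfolded protein genes 4 fell, or 7 over the list alone: DNAJB1 (-0.64), DNAJB9 (-0.86), the endoplasmic reticulum chaperone gene HSPA5 (-0.53) and HSP90AB1 (-0.49). For these 3 lists camera gave adjusted p of 0.00017, 0.00017 and 0.018, each 0.78 with an estimated correlation, and the exact test 0.081 each, with each list mean lower in 8 of 9 patients. Of 13 B cell genes 5 fell, or 9 over the list alone, among them BANK1 (-0.63) and CD79B (-0.43). The mean of the 5 tested genes of the 13 on the immature neutrophil granule list was higher in 8 of 9 patients, by 0.74 (exact adjusted p = 0.081; camera 0.0057, 0.78 with an estimated correlation). The level was low, at 2.385 under short-term and 3.121 under long-term CPAP on the log2 scale. LYZ (2768 to 1979 TPM) and S100A9, monocyte genes, fell too, as did CD1C, INSIG1, MYLIP, SOD2, MYC, JUND, PLAUR, CD44, BCL11B, POU2AF1, RPS27, RPL10A, IRF8, METRNL, MORF4L1, PPP2CA, CD82 and the uncertain RPL21. The higher genes included RCN3 (34.2 to 68.4 TPM, 0.93 ± 0.11, adjusted p = 0.0032), SCO2 (0.67), AK1 (0.78), AGER (0.70), ANKRD13D, CLDND2, SAP25, RNF31, ATP5MC1, TNFAIP2 and the oxysterol receptor gene NR1H3 (0.50). UPK3BL1 and HSPA7 rose as well, but both have near-identical copies and are uncertain. IL1B and CXCL8 differed by -1.37 and -2.37 (adjusted p 0.11 and 0.084), VEGFA by -0.33, HMOX1 by 0.10, TNF by 0.18 and IFI44L by -0.07. With covariates for monocytes, T cells and platelets 2 genes passed, and without the person block 164. Quantile normalization gave 651 higher and 555 lower genes, no low-value filter 16 genes and both times in one fit 2426, and the GC rho was 0.28.

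In the morning 46 genes were lower and 36 higher between long-term and short-term CPAP. The higher genes named, each in at least 8 of 9 patients, were PLXNB2 (0.56 ± 0.08), CLEC12A (85.1 to 127 TPM, 0.57 ± 0.09), SLC11A1 (0.55), TNFAIP2 (0.62), LILRB1 (0.48) and the G-CSF receptor gene CSF3R (0.52), with RSRP1, ZSWIM8, RCN3 (0.77) and the uncertain HSPA7. The lower genes included SMARCD2 (-0.65), PPP2CA, APH1A, CD82, MRFAP1, C19orf33, the uncertain RPL21 and EEF1G, the ribosomal gene RPL35, the naive T cell genes MAL and CCR7 (-0.40 and -0.52), BCL11B, MYC (-0.66), SOCS1 and DNAJB1. Of 52 ribosomal protein genes 2 passed, or 10 over the list alone (median -0.18; camera adjusted p 1.0e-09, 0.68 with an estimated correlation). The mean of the 16 platelet genes was lower in 7 of 9 patients and differed by -0.30 (exact adjusted p = 0.18; camera 1.6e-06, 0.68 with an estimated correlation). VEGFA, HMOX1, IL1B, TNF, CXCL8 and IFI44L differed by 0.10, 0.01, -0.54, 0.28, -1.55 and 0.22, none passing. Without the person block the count was 1, with no low-value filter 0, after the GC and length correction 450, and with both times in one fit 2426.

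Evening was compared with morning to describe time of day. In the patients 4 of 8 fixed clock genes and 2 of 2 fixed cortisol-responsive genes fell in the evening. Averaged over a patient's visits, PER1, a core repressor of the circadian clock, fell in the evening in 9 of 9 patients by 1.02 ± 0.52 on the log2 scale (SD, n = 9), TSC22D3 by 0.75 ± 0.29 and FKBP5 by 0.55 ± 0.34, and the weakly expressed PER2, PER3 and TEF (means of 2.79, 2.87 and 2.87 TPM) by 0.32, 0.33 and 0.23. The exact p of each was 0.0039, the smallest that 9 patients allow, and 0.0065 when adjusted over the 10 fixed genes. NR1D1, NR1D2, DBP and BMAL1 differed by -0.09, -0.16, 0.04 and 0.10, none passing. PER1 lies on chromosome 17 from 8140472 to 8152404, FKBP5 on chromosome 6 from 35573590 to 35728583 and TSC22D3 on chromosome X from 107713221 to 107775988. Over the same averages the glucocorticoid response and immediate early lists fell in 9 of 9 patients, each by 0.39 (exact adjusted p = 0.028). The 11 core clock genes as a list, lower in 8 of 9, differed by -0.11 (exact adjusted p = 0.10), and by -0.15 after the GC and length correction (exact adjusted p = 0.016).

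Per visit, the long-term CPAP visit gave 32 lower and 22 higher genes in the evening. PER1 fell from 114 to 43.9 TPM (-1.38 ± 0.20, adjusted p = 0.024), TSC22D3 from 671 to 345 TPM (adjusted p = 0.014), and CD69 (-1.14), CXCR4 (-0.71), NFKBIA (-1.25), DUSP1 (-1.03), JUN (127 to 81.9 TPM), JUND, PPP1R15A, KLF10, EPC1, ZFAND2A, BCL3 and CAMP, which encodes a neutrophil granule peptide, were lower too. Higher in the evening were GIMAP4 (101 to 157 TPM, 0.62 ± 0.09), GIMAP5, GIMAP7 (0.81), LTB, IL32, PIM2, LPAR6, TNFAIP8L2, TRAT1 and the chemokine receptor gene CCR2, and the heat shock gene HSPB1. At this visit NR1D1, NR1D2, BMAL1, DBP and FKBP5 differed by -0.04, -0.16, 0.02, 0.20 and -0.49, and PER2, PER3 and TEF by -0.32, -0.30 and -0.18, none passing. Camera called the glucocorticoid list lower (adjusted p 1.5e-10, 0.37 with an estimated correlation; 5 of 15 members passed, 9 over the list alone). The count was 1 without the person block and with cell mixture covariates, 0 without a low-value filter, and 98 after the GC and length correction. It was 4 in 1 fit of all 8 groups with the person as a correlated block, and the GC rho was 0.23.

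Before treatment 1 gene passed: GPR183, an oxysterol receptor that guides lymphocytes, rose from 21.8 to 41.9 TPM in 8 of 8 patients (0.92 ± 0.11, adjusted p = 0.016). It did not pass without the person block or with no low-value filter, where the count was 0, and 6 of 100 splits of the samples gave as many genes. CCR4 and NABP1 (0.79 and 0.45) and SPON2, TMEM256 and ALYREF (-0.39, -0.37 and -0.37) were nearest. PER1, TSC22D3 and FKBP5 differed by -1.24, -0.79 and -0.46, PER2, PER3 and TEF by -0.41, -0.12 and -0.23, and NR1D1, NR1D2, BMAL1 and DBP by -0.08, -0.14, 0.15 and 0.02, none passing. The GC rho was -0.28 before treatment, -0.22 under short-term CPAP and 0.13 in healthy persons. Under short-term CPAP 0 genes passed (956 unadjusted). HSPB1, LMO2 and OGFRL1 (0.43, 0.55 and 0.43) and SLC25A45, AARSD1 and TRAPPC6A (-0.36, -0.43 and -0.35) were nearest, and PER1, TSC22D3 and FKBP5 differed by -0.41, -0.42 and -0.66. PER2, PER3 and TEF differed by -0.26, -0.54 and -0.29, and NR1D1, NR1D2, BMAL1 and DBP by -0.17, -0.17, 0.14 and -0.11, none passing.

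In healthy persons 0 genes passed in 8 pairs, and only 179 had an unadjusted p under 0.05 where 444 are expected by chance. NR4A1, PAFAH1B3 and MTFP1 (1.02, 0.44 and 0.53) and FBXO4, THBS3 and SLC46A1 (-0.41, -0.37 and -0.65) were nearest. FKBP5 was lower in the evening in 7 of 8 persons (-0.58 ± 0.20) and TSC22D3 in 6 (-0.48 ± 0.20), and PER1 differed by -0.38 ± 0.37. PER2, PER3 and TEF differed by -0.10, -0.27 and -0.25, and NR1D1, NR1D2, BMAL1 and DBP by -0.06, -0.03, 0.16 and 0.03, none passing. The 13 mitochondrially encoded genes had a median of -0.27 (camera adjusted p 1.9e-14, 0.37 with an estimated correlation), lower in 7 of 8 persons, and the list mean differed by -0.28, or by -0.11 without the person of healthy morning replicate 3.

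**Figure D2:**
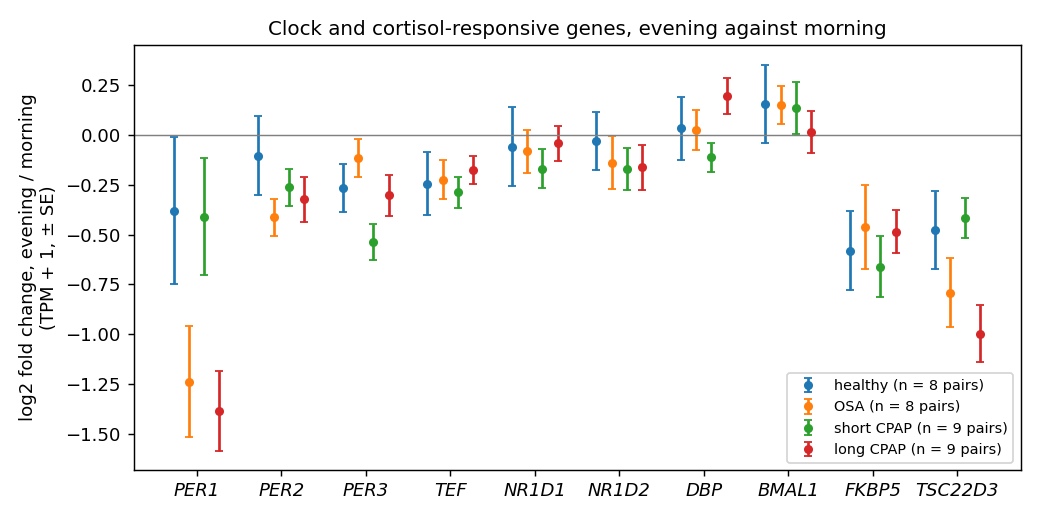
Log2 fold change (TPM + 1) of evening over morning for clock and cortisol-responsive genes in each condition, with points for the limma estimate and bars for ± SE. FKBP5 and TSC22D3 lie below 0 in all 4 conditions, and PER1 reaches -1.24 before treatment and -1.38 under long-term CPAP.

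Whether the time-of-day difference itself differed was tested for OSA against healthy and for either CPAP stage against no treatment, and 0 genes passed in each (195, 347 and 662 unadjusted), with GC rho of -0.34, 0.16 and 0.38. Immediate early genes, which respond within minutes to stimulation, had a median difference of -0.86 over 18 genes between untreated patients and healthy persons (camera adjusted p 3.1e-19, 0.16 with an estimated correlation; exact adjusted p = 0.41). When adjusted over the list alone 11 of them were lower. IER2, JUNB and EGR1 (-0.86, -0.85 and -2.19) and ZNF552, RIDA and GTPBP10 (0.84, 0.81 and 0.53) were nearest to passing there. For short-term CPAP they were P2RX7, FEZ1 and INPPL1 (0.70, 0.80 and 0.43) and NUAK2, GPR183 and IER5L (-0.51, -0.69 and -0.66), and for long-term CPAP CLDND2, ATP5ME and TRAPPC5 (0.68, 0.59 and 0.36) and PDE4DIP, MT2A and MTFR1 (-0.60, -0.46 and -0.53). The difference for PER1 was -0.86, 0.90 and -0.06 in the 3 tests, for TSC22D3 -0.31, 0.43 and -0.18 and for FKBP5 0.12, -0.24 and 0.05. The other fixed genes, PER2, PER3, TEF, NR1D1, NR1D2, BMAL1 and DBP, differed by between -0.46 and 0.15, none passing.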

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

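Among 248 combinations of a list or quality measure with a group, 18 held a library far from the others, where chance gives about 12.4. The tests on T cell, cortisol-responsive and immediate early genes, the GC and length corrections, equal library means and the reading of the splits were chosen after the results had been seen. How the corrected B cell value would be read was set before it was computed. The covariates and quantile normalization were planned, but how the share and the folds with covariates would be read was not.

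Lists are given as mean log2(TPM + 1). In the evening under long-term CPAP, replicate 3 stood at 6.60 for NF-kB inflammatory genes (next 4.96) and 8.09 for immediate early genes (next 6.62), replicate 4 at 5.63 for plasma cell genes (next 4.40), and replicate 6 at 5.59 for T cell genes (next 6.04). In the morning under long-term CPAP, replicate 5 stood at 5.83 for heat shock and unfolded protein genes (next 5.53). Under short-term CPAP in the morning, replicate 5 stood at 6.98 for adhesion genes (next 6.68) and replicate 6 at 3.77 for plasmacytoid dendritic cell genes (next 4.25). In untreated mornings, replicate 8 stood at 7.28 for oxidative phosphorylation genes (next 7.13) and 5.05 for naive T cell genes (next 5.90), and replicate 1 at -0.93 for the slope of expression on GC content (next 0.12). In untreated evenings, replicate 8 stood at 8.44 for cytotoxic genes (next 7.69). In healthy mornings, replicate 6 stood at 5.80 for interferon genes (next 4.69) and replicate 3 at 4.66 for classical monocyte genes (next 6.27). In healthy evenings, replicate 7 stood at 11.7 for ribosomal protein genes (next 11.4) and replicate 2 at 4.18 for LXR target genes (next 4.60). Genes listed at 0 numbered 13270 in healthy morning replicate 3 (next 11550), 12610 in untreated evening replicate 8 (next 11510) and 12080 in short-term CPAP evening replicate 8 (next 11180).

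B cell genes were lower under long-term CPAP than before treatment in the evening. Their list did not pass the exact test once adjusted over the lists, nor camera with an estimated correlation, and the exact p given here are unadjusted. A lower share of all lymphocytes is argued against as the whole cause in the evening: the B cell list fell further than the T cell list by -0.61 on average (8 of 9 patients, exact p = 0.027), while the T cell list itself differed by -0.22 (8 of 9, exact p = 0.023), the NK cell list by 0.02, and the morning B cell minus T cell difference of -0.50 did not pass (6 of 8, exact p = 0.125). A trend on GC content is argued against as well, because after the correction the B cell change was -0.75 (exact p = 0.0078), against -0.83 before it. A change in handling or sequencing between visits stays open, since each treatment stage was one later visit. Fewer circulating B cells under long-term treatment may be a biological explanation, untested here.

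CXCR4, CD69, RGS1, SGK1 and TIPARP were higher under short-term CPAP than before treatment in the evening, in 9 of 9 patients as a mean. A GC trend is argued against, because log2 fold changes hardly followed GC content (Spearman rho -0.003 across genes). With so little trend to remove, the mean change was 1.498 after the correction and 1.46 before. The 5 genes were chosen by passing in these same data, so their mean is no independent check. A cortisol response was not decided, because FKBP5 and TSC22D3 together differed by 0.25 (exact p = 0.094), FKBP5 by -0.22 and TSC22D3 by 0.72. A general rise of immediate early genes, such as handling before RNA extraction could bring, was not decided either, at 0.48 (6 of 9 patients, exact p = 0.051). Treatment and visit cannot be told apart here.

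Under long-term CPAP in the evening 90.7% of the passing genes were lower than before treatment. A shift of monocytes against T cells, or of platelets, is argued against as the cause, because these lists hardly shifted against each other. Before treatment and under long-term CPAP the classical monocyte means were 7.40 and 7.23, the T cell means 6.34 and 6.12 and the platelet means 7.007 and 7.035. With these covariates the share was 92.5%, but with so little to remove it could hardly move, so it adds no support. All 402 lower genes, chosen as lower in these data, stayed below 0, with a median log2 fold change of -0.51 (quartiles -0.63 and -0.44) against -0.51 before (-0.62 and -0.43). A fall of monocytes and T cells together, or a change in B cells, is not covered by these covariates. Of the 402, 167 still passed, and 199 genes in all, since the covariates use up degrees of freedom while the median SE was 0.12 in both fits. A trend on GC content and length was not decided. With the trend subtracted and each library's mean kept the share was 87.7%. The kept means, however, carry the downward shift over all genes (median log2 fold change -0.11) by construction. With the means also made equal, the correction gave 50.9%. Equal library means alone gave 52.6% and quantile normalization 58.2%. These last settings bring a balance by construction and decide nothing. A GC trend, a difference in scaling and a change in the cells all stay open.

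Splits of the samples, 100 per comparison with the real one included, bear on chance. For short-term CPAP against healthy in the evening 1 split, the real one, reached 26 genes (highest other 2). For long-term CPAP against no treatment in the evening 1 reached 443 (highest other 0), and for long-term against short-term CPAP in the morning 1 reached 82 (highest other 2). In 4 comparisons 2 splits did, the real one included: short-term CPAP against no treatment in the evening (5 genes, highest other 1024), long-term CPAP against no treatment in the morning (7, highest other 355), long-term against short-term CPAP in the evening (728, highest other 1308) and evening against morning under long-term CPAP (54, highest other 199). The share was under 0.05 for each of these 7, which speaks against chance for each taken alone. It was not adjusted over the comparisons run and rests on 100 splits each, so chance is not excluded. For evening against morning before treatment 6 splits reached 1 gene (highest other 2112), a share above 0.05, so chance cannot be excluded there either. For the 11 comparisons with 0 genes all 100 splits reached the real count by construction; the highest others were 2 and 9 (OSA against healthy, morning and evening), 1645 (short-term CPAP against healthy, morning), 10 and 4 (long-term CPAP against healthy), 5 (short-term CPAP against no treatment, morning), 1747 (time of day, healthy), 2 (time of day, short-term CPAP), and 817, 578 and 365 (differences of time of day). Why some splits called several times the real count was not tested.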

How the results depend on the processing

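The filter at 1 TPM, the GC and length corrections, equal library means and the fits without 2 healthy libraries were chosen after the data had been seen. Counts of passing genes are given where they moved by more than 1.5 times, and the cause was not tested except where stated. Depth is unknown, so what it limits cannot be given. A pseudocount of 5 gave 2 genes for long-term CPAP against healthy in the evening and 3 for short-term CPAP against no treatment in the evening, and the other 17 comparisons stayed within that range. Without a low-value filter, where between 23841 and 25332 genes are tested and the adjustment is harsher, OSA against healthy in the evening had 2 genes, short-term and long-term CPAP against healthy in the evening 7 and 2, short-term CPAP against no treatment in the evening 0, long-term CPAP against no treatment 0 in the morning and 8 in the evening, long-term against short-term CPAP 0 and 16, and evening against morning 0 before treatment and 0 under long-term CPAP. With at least 1 TPM in at least 8 libraries, OSA and long-term CPAP against healthy in the evening had 2 and 11 genes, short-term CPAP against no treatment in the evening 2, long-term CPAP against no treatment 4 and 243, long-term against short-term CPAP 36 and 318, and evening against morning under long-term CPAP 25.

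Quantile normalization gave 50 genes in the morning and 0 in the evening for short-term CPAP against healthy, 173 and 251 for long-term CPAP against no treatment, 318 and 1206 for long-term against short-term CPAP, and 85 for evening against morning under long-term CPAP. With covariates for monocytes, T cells and platelets, short-term and long-term CPAP against healthy in the evening had 70 and 2 genes, short-term CPAP against no treatment in the morning 4, long-term CPAP against no treatment 0 and 199, long-term against short-term CPAP 322 and 2, and evening against morning 6 under short-term and 1 under long-term CPAP. After the GC and length correction, OSA against healthy in the morning had 1 gene and short-term CPAP against healthy 1 in the morning and 0 in the evening. With the person block and that correction, short-term CPAP against no treatment in the evening had 9, long-term CPAP against no treatment in the morning 201, long-term against short-term CPAP in the morning 450, and evening against morning under long-term CPAP 98. Without the 2 healthy libraries, healthy morning replicate 3 and healthy evening replicate 10, short-term CPAP against healthy in the evening had 17, of which 13 were among the 26.

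Without the person block, which leaves the differences between persons in the error, 3 genes passed for short-term CPAP against no treatment in the evening, 1 in the morning and 0 in the evening for long-term CPAP against no treatment, 1 and 164 for long-term against short-term CPAP, and 0 before treatment and 1 under long-term CPAP for evening against morning. In 1 fit of all 8 groups with the person as a correlated block, OSA against healthy had 14 and 5 genes, short-term CPAP against healthy 132 in the morning, long-term CPAP against healthy 3 and 108, short-term CPAP against no treatment 4 and 11, long-term CPAP against no treatment 88 and 1301, long-term against short-term CPAP 248 in the morning, and evening against morning 1 in healthy persons, 2 before treatment and 4 under long-term CPAP. With both times of day in one fit and the person as a correlated block, which has more libraries and gives 1 count for both times, OSA, short-term and long-term CPAP against healthy had 60, 251 and 59 genes, short-term and long-term CPAP against no treatment 311 and 2418, and long-term against short-term CPAP 2426. The last 3 counts can be too high, because 1 correlation is used for all libraries of a patient. Median pair correlations were 0.52 to 0.60 for morning and evening of a patient visit, and 0.40 to 0.54 between visits at one time. The single genes named were rerun in 4 kinds of setting, and no call changed direction in these: leaving out the person block ended 126 calls, quantile normalization 17, the GC and length correction 16 with the block and 5 in fits that have none, and a pseudocount of 5 ended 1. Quantile normalization added 6 calls, a pseudocount of 5 added 2, and the GC and length correction 1 in fits without a block. Some values that had not passed changed sign, 11 of them under quantile normalization and 9 after the GC and length correction with the block.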

Other observations

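The averages over a patient's visits and the values without 1 person were chosen after the results had been seen, and the test of visits against each other was fixed before its result. Other lists also differed with time of day when averaged over a patient's visits. Plasmacytoid dendritic cell genes fell in the evening in 9 of 9 patients by 0.21 ± 0.14 (SD, n = 9; exact adjusted p = 0.028), plasma cell genes in 8 of 9 by 0.15 (exact adjusted p = 0.038) and fatty acid oxidation and fasting genes in 8 of 9 by 0.09 (exact adjusted p = 0.038). T cell genes were higher in 7 of 9 patients by 0.19, with an exact adjusted p of 0.097. In healthy evenings the 4 erythroid genes were lower in 8 of 8 persons, with a median log2 fold change of -0.78 (exact p = 0.0078, adjusted 0.23), and their mean differed by -0.65, or by -0.42 without the person of healthy morning replicate 9.

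Immature neutrophil granule genes were measured in the same way, with only 5 of the 13 list members past the value filter. Their level was low, with patient group means between 2.385 and 4.142 on the log2 scale. The 5 tested genes fell in the evening in 9 of 9 patients, with a mean change of -0.78 ± 0.60 (SD, n = 9; exact adjusted p = 0.028), and -0.79 after the GC correction. In healthy persons they were lower in 4 of 8, with a mean difference of -0.09 ± 0.85 (SD, n = 8; exact adjusted p = 0.93), which lay between -0.24 and 0.11 without 1 person. The evening minus morning values of untreated patients and healthy persons differed by -0.86 (exact adjusted p = 0.76), which did not pass, and by -0.45 without the patient of untreated morning replicate 1.

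A hypothesis was that the same genes shift between morning and evening at each patient visit. Across 8884 genes, which are not independent, evening minus morning changes correlated at r = 0.43 between the untreated and short-term CPAP visits (one-sided p = 0.010 from 1000 sign changes within persons, adjusted 0.060 over 6 pairs of conditions), 0.24 between untreated and long-term CPAP (p = 0.074) and 0.20 between short-term and long-term CPAP (p = 0.098, the largest of the 3 and the deciding value). Correlations of 0.25 to 0.30 mark the upper 5% of sign changes. By the reading fixed beforehand, a correlation within those of the sign changes counted against the hypothesis, and the deciding value lay there. That reading is not used here, because a value inside that range excludes nothing, and the hypothesis is left undecided. Changes in healthy persons correlated with those of the 3 patient visits at 0.07, 0.18 and 0.24, none passing.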
